A study of Mus musculus with 3 samples.

How the data were processed

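RNA was sequenced from 3T3-L1 preadipocytes and from 3T3-L1 cells at day 5 of differentiation with DMSO or MS417, 1 library per group. Per the labels, Trizol-extracted total RNA was depleted of ribosomal RNA and made into strand-specific total RNA libraries. The submitters' processing notes name BWA 0.7.3 and the mouse build mm9. The counting tool, the annotation release and the strand setting are not given in the sources used here, so how reads of overlapping and antisense genes were assigned is unknown.

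The authors deposited 2 tables, 1 for day 5 with DMSO against preadipocytes (16581 RefSeq transcripts) and 1 for MS417 against DMSO (18089 transcripts). Each gives the raw read count per transcript in both libraries; the values are whole numbers whose totals differ between libraries. The deposited log2 columns equal, to rounding, the log2 of the count plus 1 constant per library, and the deposited log2 ratio is their difference. That constant was 0 in the deeper library of each table, and 0.07 and 1.13 in the DMSO column of the respective tables. Every listed transcript had at least 100 counts in the larger of its libraries and none had a count of 0, so genes under that minimum in both libraries of a table are not listed there. Among genes fixed in advance, Klf15 was not listed in either table. The tables share 16371 transcripts, with the same DMSO count in each of them. Transcripts of 1 gene share reads, since isoforms are listed separately with overlapping counts. Start positions in the deposited tables count from 0 and are given here counted from 1, on mm9.

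Counts of transcripts with the same gene symbol were summed, which left 12076 and 13192 symbols. Library sizes were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, separately per table, and CPM values (counts scaled to 1 common library size, edgeR's default) were taken on these effective sizes. The value reported for a gene is the difference of log2(CPM + 1) between libraries, which understates the difference of genes with low counts. Genes needed 20 reads in the larger library, and those at least 2-fold apart were counted as higher or lower. Because there is 1 library per group, no significance test was made and no p-value is given. A 95% interval of the ratio of the counts, from the exact conditional binomial (Clopper-Pearson) distribution, covers counting error only. It was computed from the mean count per listed transcript of a symbol, so that shared reads are not counted more than once, and without the pseudocount, so that for genes with few reads it lies farther from 0 than the reported value. Intervals of shares are Wilson intervals.

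Before the data were examined, 32 gene lists were fixed, and a list with at least 5 listed members was set against 10000 random lists of its size matched on mean expression in 20 bins. A list was said to stand apart when its median lay in the outer 2.5% of those lists on either side, which describes these libraries. Brown adipocyte markers (median -0.79 over 1 gene at day 5 and -0.76 over 2 genes with MS417) and several lists of other cell types had too few listed members. At day 5 the myogenic, osteoblast, chondrocyte, macrophage and endothelial medians were 0.03, -0.80, -0.81, 0.16 and 0.14, and with MS417 they were -0.11, -0.25, 0.47, 0.38 and -0.09. The MS417 library was deeper, so low genes were listed with it mainly when their MS417 count was high, which favours positive ratios. The chondrocyte and macrophage lists had 4 and 6 listed genes there against 1 and 3 at day 5, and Cd68 had 136 reads with MS417 and 23 with DMSO. The genes named in the text were also fixed by rule: the 10 largest positive and 10 largest negative ratios of each main comparison without predicted, non-coding, histone or ribosomal protein genes, up to 4 members of each list with the largest ratios, and a set of adipogenic, lipogenic, BET and reference genes reported whatever their values. Genes named outside this rule, such as Malat1 and other non-coding RNAs, Stat1, Stat2, Nr4a1, Pde4d and members of Gene Ontology terms, were chosen after their values were seen.

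The overlap of the comparisons was set beside genes matched on expression, beside the overlap of independent lists and beside 100 simulated sets of libraries. Each set held 3 libraries drawn around the mean profile of the 3 real ones, so that they differ by counting error alone. Both ratios of a set used the same simulated DMSO library. MS417 was compared with preadipocytes on the transcripts in both tables, with TMM over all 3 libraries. GC content came from the GENCODE M21 transcripts matched by RefSeq identifier, without use of their coordinates (98.2% of symbols in the day 5 table and 98.1% in the MS417 table had a value), and the GC and length trend was removed by lowess with a span of 0.3 in statsmodels 0.14.6. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

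The procedure was tested on simulated counts drawn around the real means and library sizes, with 200 changed genes in each of 10 sets. For the day 5 comparison (12076 genes), 98.8% of genes set 3-fold higher and 99.0% of those set 3-fold lower were recovered as at least 2-fold apart, and all of the 5-fold ones. For the MS417 comparison (13192 genes) the shares were 93.8% and 96.8% at 3-fold and 99.8% and 100% at 5-fold. No unchanged gene was called in either simulation. The counting intervals held the true ratio in 95.3% of cases in both simulations, and of 200 random lists 7% stood apart in the day 5 simulation and 4.5% in the MS417 one. Those intervals were taken on simulated symbol counts without shared reads, whereas the reported ones use the mean count per transcript, which was not simulated. Such simulations hold counting error and no difference between cultures or library preparations.

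Alternatives were total-count and median-of-ratios scaling (DESeq2 1.42.0), pseudocounts of 0.2 and 5 CPM, no floor and a floor of 100 reads, thresholds of 1.5-fold and 4-fold, the highest transcript per symbol, coding genes by name, counting intervals wholly beyond 2-fold, 10 and 40 bins, and matching on the control library. After the data were seen, the deposited constants as scale, a floor of 3 CPM, removal of the GC and length trend, and an MS417 library thinned to the DMSO depth were added.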

Results

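Gene expression was measured by RNA sequencing in 3T3-L1 cells, a mouse embryonic fibroblast line committed to the adipocyte lineage, which turns into lipid-storing adipocytes when confluent cultures receive a hormone cocktail. The cocktail held 1 μM dexamethasone (a glucocorticoid), 0.5 mM isobutylmethylxanthine (IBMX, a phosphodiesterase inhibitor that raises cAMP) and 167 nM insulin. There were 3 groups with 1 library each: undifferentiated preadipocytes, cells at day 5 of differentiation with the vehicle DMSO, and cells at day 5 with 1 μM MS417 added 12 h after induction. MS417 is a small molecule that occupies the acetyl-lysine pockets of the BET proteins BRD2, BRD3 and BRD4, which bind acetylated chromatin and recruit the transcription machinery. The listed counts summed to 34976496 in the preadipocyte library and 73347618 in the MS417 library. The DMSO library summed to 33386188 in the table with the preadipocytes and 33474256 in the table with MS417, so the MS417 library held 2.19 times as many counts. With 1 library per group no difference below has a replicate check or a significance test. Ratios are given on the log2(CPM + 1) scale, genes at least 2-fold apart are counted as higher or lower, and bracketed ranges are 95% counting intervals. Those intervals cover counting error only, because reads from amplified libraries are not independent molecules, and they compare these libraries rather than the conditions.

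The first comparison, day 5 with DMSO against preadipocytes, asked how expression differed between differentiated and undifferentiated cells. Genes of fat storage were far higher at day 5. Fabp4, the fatty acid carrier of adipocytes (chromosome 3, 10204343 to 10208576, mm9), had a log2 ratio of 4.06 (4.02 to 4.24), from 20.3 to 356 CPM. Plin1, which coats lipid droplets, had 4.87, Cidec, which enlarges them, had 5.08 (chromosome 6, 113374630 to 113385749), and the adipokine gene Adipoq had 3.46. The nuclear receptor Pparg, the central regulator of adipogenesis (chromosome 6, 115311239 to 115440419), stood at 2.47 (2.39 to 2.62), and Cebpa, the transcription factor that acts with it (chromosome 7, 35904312 to 35906951), at 2.02 (1.96 to 2.29). Matrix and interferon-stimulated genes were lower as groups, and the gene with the largest negative ratio was Sfrp2, which encodes a secreted Wnt antagonist, at -4.41. Among 12076 gene symbols, 961 were at least 2-fold higher and 1023 at least 2-fold lower at day 5.

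Of 14 listed adipocyte markers and secreted factors, 13 were at least 2-fold higher and none lower, with a median log2 ratio of 3.33. The remaining member, the insulin-regulated glucose transporter gene Slc2a4, stood at 0.99, and Agt, which encodes angiotensinogen, was among the highest at 4.55. Slc2a4 was low, at 1.75 CPM in preadipocytes and 4.30 with DMSO when all 3 libraries were scaled together. At such levels the added 1 CPM shrinks the ratio. Random lists of the same size matched on expression had medians between -0.47 and 0.45 in 95% of 10000 draws. Genes of triglyceride synthesis and lipid droplets had a median of 2.52 and 12 of 15 members higher, among them Dgat2, which makes triglyceride, at 3.87 and Acsl1, which activates fatty acids, at 3.42. The 6 lipolysis genes had a median of 2.14, with Pnpla2, the first lipase of triglyceride breakdown, at 2.38, its activator Abhd5 at 2.31 and its inhibitor G0s2 at 3.20. The 18 adipogenic transcription factors were mixed, with 7 higher, 2 lower and a median of 0.64. Nr1h3, which encodes the oxysterol receptor LXRα, stood at 2.68, Zbtb16 at 4.29 and Cebpb at 1.36, whereas Srebf1 at 0.60 and Mlxipl at 0.42, the regulators of lipogenic genes, were within 2-fold.

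De novo fatty acid synthesis did not stand apart as a list, with a median of 0.39 over 19 genes against a matched range of -0.40 to 0.41. The stearoyl-CoA desaturase gene Scd1 was higher at 1.33 (1.29 to 1.36) and Fads2, another desaturase, lower at -1.16. Fasn at 0.54, Acaca at 0.36 and Acly at -0.52, which encode the enzymes from citrate to palmitate, were within 2-fold. Lpl, the lipase that frees fatty acids from lipoproteins, was already abundant in preadipocytes at 624 CPM and stood at 1.04 (1.02 to 1.07). Glycolysis and glucose uptake did not stand apart, at 0.33 over 18 genes. Genes of mitochondrial metabolism and of NADPH supply were higher as groups. Fatty acid oxidation had a median of 0.90 with Acadm at 2.61, the citrate cycle 0.88 with Idh3a at 1.63, and the pentose phosphate and NADPH list 0.89 with the pyruvate carboxylase gene Pcx at 3.13 (3.08 to 3.18). Oxidative phosphorylation had 20 of 36 members higher and a median of 1.03, led by the cytochrome c gene Cycs at 1.93, and 17 of 76 ribosomal protein genes were higher with a median of 0.81. Other coding transcripts under 800 nt, without ribosomal protein and histone genes, were also higher in the DMSO library, with a median of 0.70. After a trend on GC content and transcript length was removed, 3 of 36 oxidative phosphorylation genes were higher with a median of 0.51, and 3 of 21 citrate cycle genes instead of 8. Of the ribosomal protein genes 3 were then higher, with a median of 0.21 that no longer stood apart. The 57 replication-dependent histone genes had a median of 0.41, with Hist1h4i at 1.41, and -0.20 after the same correction, a change of sign. Their near-identical copies make values of single histone genes uncertain.

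The pooled list of glucocorticoid and cAMP responsive genes was higher, with 8 of 12 genes past 2-fold and a median of 1.36. It does not tell the 2 arms of the cocktail apart: Pde4b stood at 1.23, Nr4a1 at 0.57 and Pde4d at -0.27. Fkbp5, a glucocorticoid receptor co-chaperone, stood at 4.60 (4.56 to 4.74), Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, at 4.17 (4.12 to 4.26) and the metallothionein gene Mt2 at 2.55. Stress response and serine synthesis genes had a median of 0.89, with the mitochondrial folate enzyme gene Mthfd2 at 2.81. Myc stood at 1.86 (1.66 to 2.18), although the immediate early list as a whole did not stand apart, with a median of -0.14. The insulin signalling list and the p53 list did not stand apart either, at 0.09 and -0.03, nor did the BET and P-TEFb list at -0.25, though Irs1, the insulin receptor substrate gene, stood at -1.73 and Sorbs1 at 1.69.

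Lower at day 5 were the preadipocyte and fibroblast markers, with 6 of 13 genes past 2-fold and a median of -0.81. Dlk1, the epidermal growth factor-like protein of preadipocytes (chromosome 12, 110691665 to 110701546), was at -2.28 (-2.44 to -2.16) and the Wnt ligand gene Wnt5a at -2.21. Interstitial matrix had 11 of 27 genes lower and a median of -0.79, with Thbs1 at -3.55, Tnc at -3.07, Lum at -3.02 and the fibrillin gene Fbn1 at -2.22. Contractile genes had a median of -0.78, with Myl9 at -1.81 and Tpm1 at -1.78. The basement membrane list was centred at 0.00, yet its collagen genes Col4a1 and Col4a2 were higher at 1.57 and 1.29. Cell cycle genes had 9 of 33 members lower, none higher and a median of -0.52, with the mitotic genes Cenpf at -2.79 and Mki67 at -2.40. Interferon-stimulated genes had 14 of 18 members lower and a median of -1.63, with Ifit2 at -2.90, Ifit3 at -2.54 and Ifit1 at -2.40. NF-kB and inflammatory genes had 6 of 15 lower and a median of -0.84, led by the chemokine gene Cxcl5 at -3.52, while the acute phase gene Saa3 was higher at 2.67. Cholesterol synthesis genes had a median of -0.55, with Srebf2, the regulator of that pathway, at -1.19.

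Leaving aside predicted, non-coding, histone and ribosomal protein genes, the 10 largest positive ratios belonged to Fam107a at 7.15, Aldh1a7 at 6.90, Ear1 at 6.57, Ear2 at 6.13, Ear10 at 5.97, Map7d2 at 5.60, Glul at 5.41, Sult1a1 at 5.40, Hmgcs2 at 5.12 and Cidec. Glul encodes glutamine synthetase and Hmgcs2 the mitochondrial enzyme of ketone body synthesis. The Ear ribonuclease genes and Aldh1a7 have near-identical relatives whose reads can be shared, so their single values are uncertain. After Sfrp2, the largest negative ratios were Timp3 at -3.62, Thbs1, Cxcl5, Trim30d at -3.40, Ptchd1 at -3.13, the antiviral gene Oas2 at -3.10, Gvin1 at -3.10, Tnc and Kif26b at -3.05. The reference genes Actb and Gapdh were close to 0, at -0.08 and -0.14. Markers of other cell types were few: of 9 listed myogenic, chondrocyte, macrophage and endothelial genes, Lyz2 at -1.29 was the exception to values within 2-fold. The osteoblast-associated genes Spp1 and Runx2 were lower at -2.44 and -1.54. Removing the GC and length trend left 705 genes higher and 728 lower, of which 549 and 593 were among the genes called before.

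**Figure D1:**
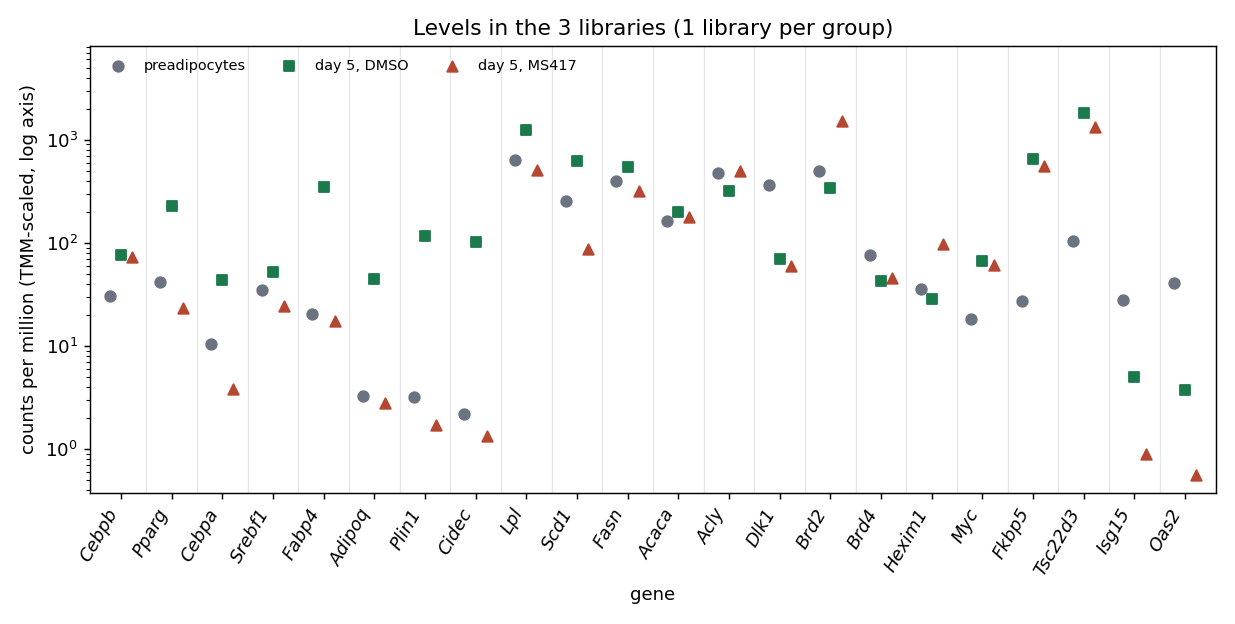
Level of 22 genes in each of the 3 libraries, in CPM on a log axis, with grey circles for preadipocytes, green squares for day 5 with DMSO and red triangles for day 5 with MS417. Each point is 1 library without an error bar; Fabp4 stood at 20.7, 347 and 17.4 CPM in that order, and Fkbp5 at 27.2, 656 and 562 CPM.

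The comparison of MS417 with DMSO, both at day 5, asked what the BET inhibitor did to expression during differentiation, in particular to genes of lipid and carbohydrate metabolism. The adipocyte genes were far lower with MS417. Plin1 had a log2 ratio of -5.46 (chromosome 7, 86866050 to 86877662), Cidec -5.48, Fabp4 -4.27 (-4.43 to -4.26), the fatty acid transporter gene Cd36 -4.28 (-4.49 to -4.18) and Adipoq -3.59. Pparg was lower at -3.25 (-3.42 to -3.20), from 226 to 22.9 CPM, and Cebpa at -3.24, whereas Cebpb, which acts upstream of both, stood at -0.08 (-0.15 to -0.01). Brd2, which encodes a target of the drug (chromosome 17, 34248964 to 34259552), was higher at 2.15 (2.10 to 2.20), and so was Hexim1, an inhibitor of the elongation factor P-TEFb (chromosome 11, 102977639 to 102981038), at 1.69 (1.63 to 1.83). Of 13192 symbols, 874 were at least 2-fold higher and 1125 at least 2-fold lower with MS417.

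Of 15 adipocyte markers and secreted factors, 14 were lower and none higher, with a median of -2.30 against a matched range of -0.36 to 0.36. Triglyceride synthesis and lipid droplet genes had 12 of 16 members lower and a median of -2.25, with Dgat2 at -3.53 and Acsl1 at -3.24. The lipolysis median was -1.71, with G0s2 at -3.88 and the hormone-sensitive lipase gene Lipe at -2.90. Among the adipogenic transcription factors 9 of 18 were lower, 2 were higher and the median was -0.79, with Nr1h3 at -3.63, Srebf1 at -1.09 and Mlxipl at -0.48. Fatty acid synthesis did not stand apart as a list, with a median of -0.30 and 4 of 19 genes lower, but did so at -0.40 after the GC and length correction. Scd1 was the member farthest below at -2.85 (-2.90 to -2.82), and Fasn at -0.82, Acaca at -0.21 and Acly at 0.61 were within 2-fold. Lpl stood at -1.34 and Slc2a4 at -1.33.

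Glucose and mitochondrial pathways were lower by smaller amounts. Glycolysis and glucose uptake had 6 of 18 genes lower and a median of -0.69, with Ldhb at -2.13, the triose phosphate isomerase gene Tpi1 at -1.62 and Hk2 at -1.10, whereas Gapdh stood at 0.38. The pentose phosphate and NADPH list had a median of -0.67, with Pcx at -1.80 and G6pdx, the entry enzyme of the pathway, at -1.24. The citrate cycle list had a median of -0.54 with none of its 21 genes past 2-fold, and fatty acid oxidation -0.75 with Ech1 at -2.92. Oxidative phosphorylation had 7 of 36 lower and a median of -0.59, which was -0.42 after the GC and length correction, with Ndufa9 at -1.66 and Atp5o at -1.50. Coding transcripts under 800 nt, without ribosomal protein and histone genes, were also lower against the DMSO library, with a median of -0.28 outside the matched range of -0.09 to 0.06. Cholesterol synthesis had 6 of 22 lower and a median of -0.64, with Cyp51 at -2.24 and the farnesyl diphosphate synthase gene Fdps at -2.08. Stress response and serine synthesis genes had a median of -0.66, with the cystine transporter gene Slc7a11 at -2.31 and Xbp1 at -1.82, although Ddit3, a stress-induced transcription factor, was higher at 1.46. Replication-dependent histones had 21 of 58 members lower and a median of -0.82, or -0.44 after the correction, while the near-identical Hist2h3c1 and Hist2h3c2 were higher at 2.98 and 2.58. Ribosomal proteins stood at -0.20 with no gene past 2-fold, and at 0.09 after the correction.

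Interferon-stimulated genes were lower again with MS417, with 15 of 17 members past 2-fold and a median of -2.11, although Ifit2, the lowest member at day 5, stood at 0.74. Ifi44 stood at -3.19, Oasl2 at -3.12, the deconjugase gene Usp18 at -2.83 and Irf9, a subunit of the interferon-activated complex, at -2.74 (-2.98 to -2.65). Immediate early genes were higher, with 9 of 13 past 2-fold and a median of 1.09, led by Fos at 2.34 (2.33 to 2.78), Jund at 1.64 and Ier3 at 1.42. Myc stood at -0.15 (-0.30 to 0.00). In the list of BET proteins and P-TEFb components, 2 of 10 were higher and Hexim2 was lower at -2.44. The median of 0.49 lay just inside the matched range of -0.48 to 0.50, and stood apart under 4 of the alternatives, such as the GC and length correction at 0.54, with Brd3 at 0.66 and Brd4 at 0.09 (-0.03 to 0.22). Cell cycle genes did not stand apart, with a median of 0.23, or 0.21 after the correction. Of 33 members 5 were higher, Cenpf at 1.99, Bub1 at 1.60 and Mki67 at 1.43 among them. In the other direction 1 was lower, and 15 had negative ratios. The p53 list did not stand apart, with a median of -0.25 and Cdkn1a, the cell cycle inhibitor gene, at -2.08.

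The preadipocyte and fibroblast list did not stand apart, at a median of -0.23. Dlk1 stood at -0.27 (-0.44 to -0.11), Pdgfra and Thy1 were lower at -2.33 and -1.88, Nr2f2 was higher at 1.24, and Ly6a, which has near-identical relatives, stood at -4.23. Interstitial matrix genes had 9 of 27 members lower, 2 higher and a median of -0.23, with Dcn at -3.58, Col6a3 at -3.32 and Postn at -2.19 lower and Thbs1 higher at 1.81. Basement membrane had a median of -0.66, with Col18a1 at -1.81. Contractile genes had a median of -0.13, with Myl9 at -3.07. The NF-kB list was at -0.15, with the monocyte chemokine gene Ccl2 higher at 1.66. Glucocorticoid and cAMP targets had a median of -0.25, with the phosphodiesterase gene Pde4b lower at -1.88, Zbtb16 lower at -2.25 and Mt1 higher at 1.35. Insulin signalling had a median of -0.15 and no gene past 2-fold. The macrophage list, at 0.38, did not stand apart, and low genes like its members are listed mainly when their MS417 count is high. Among the few listed myogenic, osteoblast, chondrocyte and endothelial genes the muscle filament gene Des at -2.49 was the member past 2-fold.

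With the same kinds of genes left aside as at day 5, the largest negative ratios were Hmgcs2 at -5.53, Cidec, Plin1, Ear1 at -5.41, the haptoglobin gene Hp at -5.28, the interleukin-1 receptor antagonist gene Il1rn at -5.14, Enpp2, which encodes autotaxin, at -5.09, Ear10 at -4.95, Ear2 at -4.67 and Rarres2, which encodes the adipokine chemerin, at -4.64. The largest positive ratios were smaller: Efnb2, an ephrin ligand gene, at 3.34 (3.33 to 3.73), Ogfrl1 at 2.72, Gdf11, a growth factor of the TGF-β family, at 2.68, Mfap3l at 2.62, Nanos1 at 2.55, Lrrtm2 at 2.35, Fos, Slc45a3 at 2.32, Mybl1 at 2.31 and the stress gene Gadd45b at 2.30. Actb stood at -0.06. Among the genes left aside, non-coding nuclear Malat1 stood at 3.83 and took 4.31% of the counts with MS417 (Wilson interval 4.31 to 4.32) against 0.301% with DMSO (0.299 to 0.302, in the table with preadipocytes). Removing the GC and length trend left 633 genes higher and 1048 lower, of which 510 and 915 were among those called before.

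**Figure D2:**
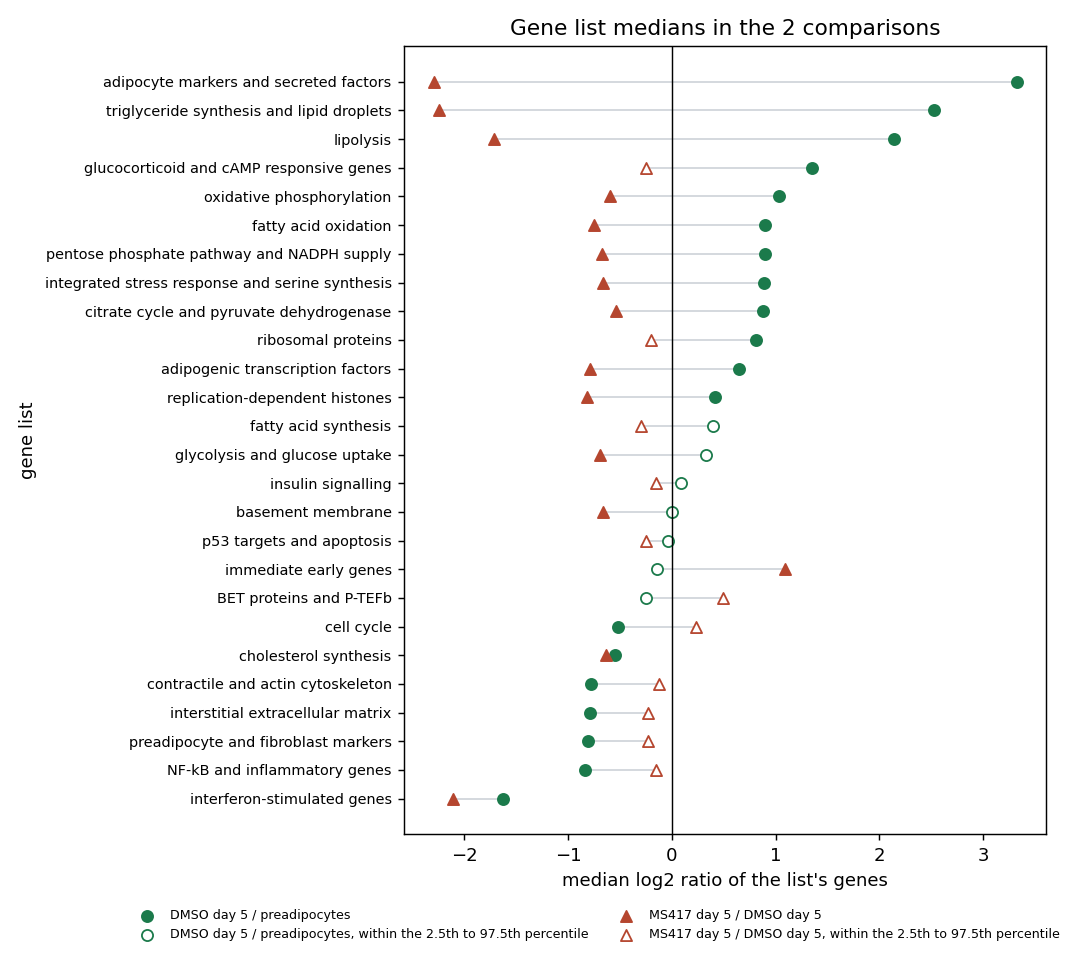
Median log2 ratio of each gene list with at least 5 listed members, for day 5 with DMSO over preadipocytes (green circles) and MS417 over DMSO (red triangles). Filled symbols lie in the outer 2.5% of 10000 matched random lists on either side, and the adipocyte markers moved farthest apart, at 3.33 and -2.30.

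Setting the comparisons side by side asked how much of the day 5 expression pattern was missing with MS417. Of the 961 genes higher at day 5, 368 were at least 2-fold lower with MS417, or 38.3% (Wilson interval 35.3 to 41.4), among them Pparg, Cebpa, Fabp4, Plin1 and Cidec. Genes matched on expression gave 9.26% (7.60 to 11.1), and independent lists would share 90.7 genes. In the other direction, 249 of the 945 lower genes present in both tables were higher with MS417, or 26.3% (23.6 to 29.2), against 7.09% of matched genes and 66.8 for independent lists. Thbs1, Cenpf and Mki67 were of this kind. Just 12 genes were higher in both comparisons, Mt1, Dusp1, Col4a2 and Slc45a3 among them, against 68.0 for independent lists. Lower in both were 101 genes, including Oasl2, Ifi44, Dcn and Myl9, or 10.7% of the 945, close to the 9.42% of matched genes (7.51 to 11.1) and to the 89.2 genes of independent lists.

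Both comparisons use the same DMSO library, so chance alone makes their ratios oppose each other, and part of the excess can come from that shared control. For the same reason chance can give fewer genes moving the same way than matched or independent lists do. Those lists are thus no chance level for the 12 or the 101 genes. In 100 simulated sets of 3 libraries that differed by counting error alone, no gene was 2-fold higher at day 5 or 2-fold lower with MS417, and the lists shared no gene. Those sets hold no difference between cultures or library preparations, so they do not show how much opposition such a difference in the DMSO library would create. Across 11920 genes, which are not independent replicates, the covariance of the ratios was -0.30 against a simulated -0.0035 (Pearson r -0.47 and Spearman rho -0.45, with a simulated r of -0.59). A covariance of -0.21 remained after the GC and length trend was removed, when the shares were 45.2% and 17.1%.

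**Figure D3:**
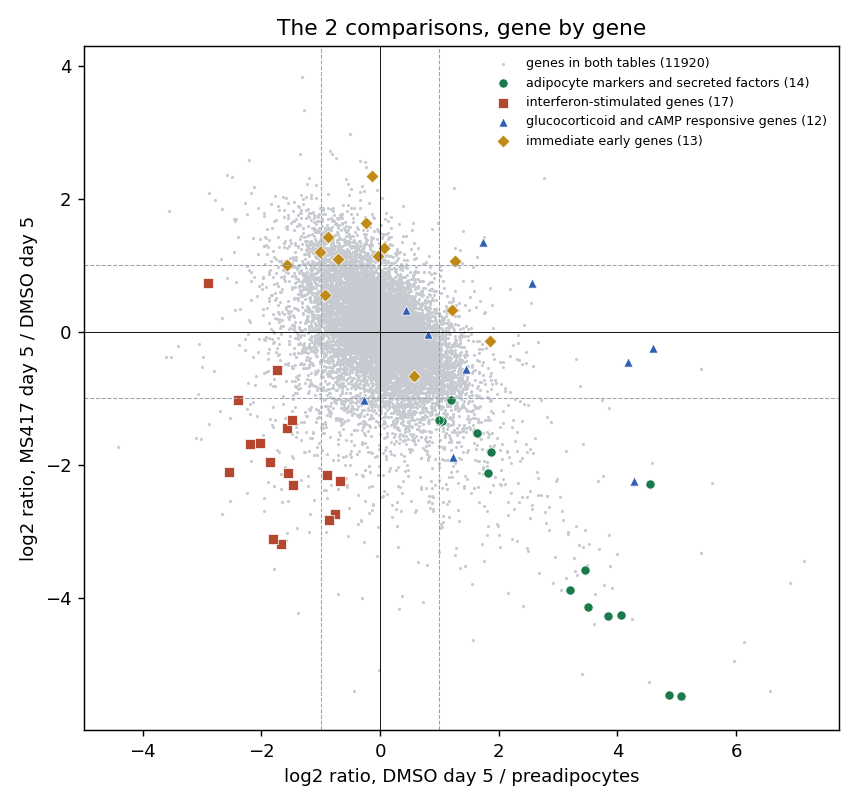
Each point is 1 of 11920 genes, with its log2 ratio of day 5 with DMSO over preadipocytes on the x axis and of MS417 over DMSO on the y axis; dashed lines mark 2-fold. Adipocyte markers lie at the lower right, Plin1 at 4.87 and -5.46, interferon-stimulated genes at the lower left, and Fkbp5 near the x axis at 4.60 and -0.25.

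MS417 cells were also set against the preadipocytes, on the transcripts listed in both tables, to see which genes stayed at the undifferentiated level. Adipocyte markers were close to it: their median was -0.34 over 14 genes, at the 8.82nd percentile of matched lists, with Fabp4 at -0.24, Adipoq at -0.17, Plin1 at -0.63 and Cidec at -0.44. Agt, at 2.22, was the exception past 2-fold on this scale. Some members had few counts in both libraries, where the added 1 CPM pulls ratios toward 0, so their closeness is uncertain. G0s2 had 1.72 CPM in preadipocytes and 0.65 with MS417, and Cidec 2.18 and 1.34, with a counting interval of -1.15 to -0.25. The adipogenic transcription factors stood apart at -0.55, with Pparg at -0.81 and Cebpa at -1.26, while Cebpb remained higher at 1.25 (1.18 to 1.37). Triglyceride genes had a median of -0.32 with none of 15 past 2-fold. Of 957 genes higher at day 5 with a value here, 706 were within 2-fold of the preadipocytes with MS417, 218 were still higher and 33 were lower, and their median went from 1.29 to 0.51. Of the 1023 lower genes 945 had a value here. Of these, 494 were within 2-fold and 446 still lower, and the median went from -1.27 to -0.91. The others were too low with both DMSO and MS417 to be listed, so the count still lower may be too small.

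Some genes higher at day 5 with DMSO were also higher with MS417 than in preadipocytes. Of 12 glucocorticoid and cAMP targets 6 were higher and 1 lower, with a median of 1.43, Fkbp5 at 4.32 (4.27 to 4.46), Tsc22d3 at 3.68, Mt2 at 3.26 and Mt1 at 3.05, whereas the phosphodiesterase gene Pde4b, at 1.23 with DMSO, stood at -0.69. Glul was still higher at 4.81, Pcx at 1.30, Saa3 at 2.48 and Lcn2 at 1.95. Ribosomal proteins had 7 of 76 members higher and a median of 0.60, or 1 member and 0.37 after the GC and length correction. Oxidative phosphorylation had a median of 0.35, which was 0.17 and inside the matched range after it.

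Immediate early genes, which did not stand apart at day 5 with DMSO, were above the preadipocyte level with MS417, at a median of 1.07 with Fos at 2.18. Other groups were below that level. All 17 listed interferon-stimulated genes were at least 2-fold lower, with a median of -3.73, Oasl2 at -4.98 and Ifi44 at -4.92. Interstitial matrix had 15 of 27 lower and a median of -1.31, with Dcn at -5.41, Lum at -4.68 and Tnc at -4.05, whereas Col4a1 was higher at 2.51. Preadipocyte and fibroblast markers had a median of -1.41, with Pdgfra at -2.93, Dlk1 at -2.59 and Wnt5a at -2.08. Contractile genes had 9 of 15 lower, with Myl9 at -4.93 and Acta2 at -2.90. Cell cycle genes had 7 of 33 lower, 2 higher and a median of -0.39, with Mki67 at -1.01 and Cenpf at -0.83. Cholesterol synthesis had 13 of 22 lower and a median of -1.12, with Fdps at -2.37, the lipoprotein receptor gene Ldlr at -2.27 and Srebf2 at -1.67. In all, 602 of 11915 genes were at least 2-fold higher and 1256 at least 2-fold lower in MS417 cells than in preadipocytes.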

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

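The deposited-constant scale, the 3 CPM floor, the GC and length correction and the thinning were chosen after the data were seen. Of 118 recomputed gene counts and shares, 93 stayed within 1.5 times the reported count or inside the reported interval. Of 999 recomputed list medians, 983 stayed on the same side of the percentile limits, though 9 of them, in lists that did not stand apart, changed sign. No named gene past 2-fold changed direction. The GC and length correction moved 258 named ratios beyond counting error and left 170 within it, and adding 5 CPM moved 173 and left 258. Over all settings 4359 of 4937 stayed within it, a share raised by settings that move nothing. Total-count scaling moved the median of all genes by at most -0.08, and median-of-ratios scaling by at most 0.02. Removing the floor, or raising it to 100 reads, changed nothing in the comparisons with DMSO because the deposited minimum is 100. Leaving out a replicate was not possible, and no paired analysis was possible because each group has 1 library.

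At 1.5-fold, day 5 had 2353 genes higher and 2491 lower, MS417 2298 and 2443, and MS417 against preadipocytes 1966 and 2442, and the opposed shares were 45.5% and 40.3%. At 4-fold the counts were 149 and 94, 41 and 269, and 59 and 310, with shares of 57.0% and 8.11%; a stricter limit passes fewer genes by construction. With 5 CPM added, 594 genes were lower at day 5, 547 higher and 694 lower with MS417, and 376 higher against preadipocytes, and the share of lower genes that were higher with MS417 was 19.9%. That share was 29.8% with 0.2 CPM and 22.9% where the counting interval lay beyond 2-fold. Large pseudocounts shrink low genes by construction. Total-count scaling gave 810 genes higher and 1231 lower at day 5, and the deposited constants 811 and 1227. The GC and length correction gave shares of 45.2% and 17.1%.

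Among lists, the correction turned the histone median at day 5 from 0.41 to -0.20, and ended the standing of ribosomal proteins at day 5 (0.21, 95.2nd percentile) and of oxidative phosphorylation against preadipocytes (0.17). With it, fatty acid synthesis (-0.40) and interstitial matrix (-0.36) stood apart with MS417, as did NF-kB genes against preadipocytes (-0.38) and BET and P-TEFb genes with MS417 (0.54). The latter also stood apart with the 3 CPM floor (0.49), at equal depth (0.53) and when matched on the control library (0.49), as did ribosomal proteins with MS417 in 10 bins (-0.20). Matching on the control library did the same for fatty acid synthesis (0.39) and glycolysis (0.33) at day 5, and for adipocyte markers (-0.34), the citrate cycle (0.33) and the stress response list (0.34) against preadipocytes. The cause of these changes was not tested.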

Other observations

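Gene groups outside the fixed lists were looked for in 1572 Gene Ontology terms with 10 to 100 listed genes, and the terms and genes below were chosen after their values were seen. With MS417, 194 terms lay in the lowest 2.5% of matched lists and 107 in the highest, where chance gives 39.3 on each side on average. Terms share genes, so such counts can vary widely around that average, and their spread was not estimated. Complement activation had 7 of 12 genes at least 2-fold lower and none higher, with a median log2 ratio of -1.36. C1ra, C1s and C3, which encode proteases and the central protein of the cascade, stood at -2.31, -2.15 and -1.51 (-1.52 to -1.49). Glutathione transferase activity had 12 of 18 genes lower, with a median of -1.24, or -0.91 after the GC and length correction. At day 5 over preadipocytes 4 of 15 were higher and 1 lower, and the median was 0.75, or 0.12 after the correction. Gsta3 stood at 2.85 at day 5 and -2.98 with MS417, Mgst3 at 2.04 and -2.30, Mgst1 at 1.00 and -1.98, and Gstm5 at 1.13 and -2.59. Gstt1 was lower in both, at -1.40 and -1.51. Relatives in this family can share reads. The proteasome core had a median of 0.91 at day 5, or 0.40 corrected, and -0.60 with MS417. Its interferon-induced subunit gene Psmb8 was lower in both comparisons, at -1.46 and -1.91, and Psmb10 stood at -0.58 and -1.64.

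In the opposite direction, genes of mitotic chromosome condensation had 3 of 11 members higher and a median of 0.86 with MS417. The 3 were the condensin genes Smc2, Smc4 and Ncapg at 1.69, 1.57 and 1.44, after -1.41, -0.85 and -1.23 at day 5, while the condensin genes Ncaph at 0.89, Ncapd3 at 0.77 and Ncapd2 at -0.20 were within 2-fold. Centriole genes had 7 of 38 members higher and a median of 0.67, with the pericentrin gene Pcnt at 1.56. The regulation of DNA replication term had 6 of 10 genes higher and a median of 1.19, with the cohesin gene Smc3 at 1.69, the licensing inhibitor gene Gmnn at 1.59 and Pcna at 1.11. The condensation, centriole and replication medians were 0.79, 0.44 and 0.84 after the GC and length correction. Against preadipocytes Smc2 stood at 0.25, Ncapg at 0.18, Ncapd2 at -1.20 and Gmnn at 1.29. The fixed cell cycle list stood apart below the preadipocyte level, at a median of -0.39.

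The patterns below and their tests were chosen after the data were seen, and the prediction of each test was written before its result.

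The DMSO library was rich in short structured RNAs. Of 40 listed non-coding RNAs under 350 nt, 33 were at least 2-fold lower in the MS417 library, with a median log2 ratio of -2.15, while the 34 listed in both tables had a median of 0.04 between MS417 and preadipocytes. By length, 25 of 25 were lower from 100 to 200 nt and 7 of 10 from 200 to 350 nt. Under 100 nt it was 1 of 5, with a median of -0.12. Rmrp, the RNA of ribonuclease MRP, took 2.80% of counts with DMSO in the table with preadipocytes, 0.690% in preadipocytes and 0.578% with MS417. A candidate explanation is an excess of all short transcripts in that library: 334 short mRNAs had a median of -0.28 between MS417 and DMSO, below the matched range of -0.09 to 0.06 but short of the -0.5 set as its mark. The same mRNAs had a median of 0.70 between DMSO and preadipocytes, which goes with it, and 0.37 between MS417 and preadipocytes. Size selection of the DMSO library and a real difference in these RNAs cannot be told apart, because that value falls between the limits set for either and each group has 1 library.

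Interferon-stimulated genes were lower at day 5 and lower again with MS417. A GC or length trend would have brought the median above -1 once removed. It was -2.07 over the 16 genes with a GC value, which argues against that trend as the whole cause. The 95% interval from the ranked genes was -2.62 to -1.25. It treats the genes of 1 list as independent and covers no difference between cultures or library preparations. With the MS417 library thinned to equal depth the median was -2.13, but thinning removed none of the 17 genes and hardly moves scaled ratios, so it decides nothing about depth. What else stays open, untested with 1 library per group, is an effect of the inhibitor on basal interferon signalling or a difference between cultures. Irf9 at -2.74, Stat1 at -2.25 and Stat2 at -0.58 belong to the list itself, so their values add no separate support.

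Malat1, Neat1 and Kcnq1ot1, all retained in the nucleus, were higher with MS417 at 3.83, 2.67 and 2.17. With the GC and length trend removed their median was 2.75, from 1.27 for Kcnq1ot1 to 3.41 for Malat1, which argues against that trend as the whole cause, though it took away much of the Kcnq1ot1 difference. A larger share of nuclear RNA in the MS417 library and a response of single genes to BET inhibition cannot be told apart. Of the other nuclear RNAs 7 had a median of -0.13, which met the outcome written beforehand as speaking against a larger nuclear share. That does not decide it, because they ranged from -1.24 for Pvt1 to 0.88 for Tug1 and some had few reads, such as Meg3 with 110 and 71. Dnm3os, a non-coding RNA outside that set, stood at 2.58. Malat1 at 2.48 and Neat1 at 1.83 over preadipocytes, with Kcnq1ot1 at 0.01, leave both open.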
